A study of Mus musculus with 3 samples.

How the data were processed

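Total RNA of mouse bone marrow-derived macrophages was measured on 3 Agilent 2-colour arrays, each of which held RNA of adiponectin-treated cells in one dye and RNA of untreated cells in the other, so that 6 RNA samples gave 3 treated over untreated ratios. Per the labels, the macrophages came from C57BL/6J mice, were matured in medium conditioned by L929 cells (a fibroblast line that secretes the growth factor CSF-1), were kept in low serum and were then left untreated or given adiponectin at 12 µg/ml for 18 h; the RNA extraction text of the labels gives the same figure in mg/ml, and the unit used here is that of the treatment text and the sample labels. The labels call the arrays biological replicates 1, 2 and 3. Per the labels, the treated RNA was in Cy3 on replicates 1 and 3 and in Cy5 on replicate 2, and the direction of every ratio was taken from these labels. The dye orientations were unequal (2 arrays against 1), so a gene-specific dye effect was reduced but not cancelled in the mean. With a dye term, which leaves 1 residual degree of freedom, 45 genes had a dye coefficient past the threshold in limma.

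Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 10.7.3.1 with its protocol for 2-colour expression arrays, and the array design was placed on mouse build mm9. Per the file headers, the deposited intensity columns hold the median pixel brightness of each spot and of its local background in each dye, with no normalization. The deposited processed signals are, per the file headers, background-subtracted and dye-normalized by the scanner software, and the deposited log10 ratio is that of the Cy5 over the Cy3 processed signal. A further deposited table holds the authors' log2 values per array. How the authors made that table is not given in the sources used here, so its direction and centring were found by comparison with the scanner values. Its columns correlated with loess-normalized ratios without background correction, turned to treated over untreated, at r = 0.994, 0.990 and 0.992 across spots, with slopes of 1.04, 1.08 and 1.05, and its medians were -0.00041, -0.0049 and -0.00064. The table was thus already turned to treated over untreated on all arrays, including the dye-swapped replicate, and its background handling stays unknown.

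Median spot signals were used, since these are the signal columns of the scanner files used here. They were corrected for background with normexp (offset 50) and normalized within each array with loess in limma 3.58.1 under R 4.3.3, with control spots at weight 0, and each log2 ratio was turned to treated over untreated. Spots marked as outliers by the scanner software were left out (323, 303 and 299 on replicates 1, 2 and 3), and no spot was saturated. Control spots were left out after normalization, and spots of the same probe were averaged. Probe accessions were named through a RefSeq table of assembly GRCm38.p6, used for symbols alone. Of 55681 probes, 27235 matched 1 symbol and together covered 20660 genes, while 28446 had no symbol, 16194 of them named only by a genomic region. A probe was kept when it was well above background in at least 3 of the 6 channel readings, and each gene was represented by 1 probe, the one with the highest mean intensity. This left 13179 genes, and 7481 genes were not measured. Of 3391 genes with several measured probes, 860 had probes of opposite mean sign, and 104 called genes had probes beyond 0.5 on the log2 scale in opposite directions.

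The 3 ratios of each gene were tested against 0 with limma's lmFit and eBayes, and p-values were adjusted with the Benjamini-Hochberg method over the 13179 genes. A gene was called at an adjusted p under 0.05. The prior had 6.22 degrees of freedom beside 2 residual ones, and the median standard error (SE) was 0.088 on the log2 scale. Every SE given is limma's moderated one, which draws the variance of a gene towards a prior over all genes. It is not the observed spread of the 3 arrays. The standard deviation over the arrays was 0.99 for Saa3 (moderated SE 0.29) and 0.011 for Ptpro (moderated SE 0.079). Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 23 lists. The estimated correlation rests on the 2 residual degrees of freedom. A call lost with it therefore cannot tell correlated genes from too few arrays. The same tests were run on markers of 12 cell types, 8 of which had at least 5 measured members. The lists cover inflammatory cytokines and chemokines, NF-kB targets, negative regulators of Toll-like receptor signalling, inflammatory effectors, alternative activation, interferon-stimulated genes, antigen presentation, Toll-like receptors, LXR targets, lipid uptake, cholesterol biosynthesis, fatty acid oxidation, oxidative phosphorylation, glycolysis, NRF2, lysosome, the unfolded protein response, cell cycle, matrix, complement and Fc receptors, chemokine and growth factor receptors, adiponectin signalling and common reference genes.

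The gene lists, the cell type markers, the tests and the rule for named genes were fixed before the data were examined. The rule named the 12 called genes with the largest rise and the 12 with the largest fall among those with the same sign in all 3 arrays, leaving out predicted genes, up to 4 called members with the largest absolute change in each list, and 10 fixed genes (Adipor1, Adipor2, Cdh13, Tnf, Il6, Il10, Arg1, Nos2, Irak3 and Abca1). Other list members are given as values of their list. A few genes that the rule names are not reported here. Further lists for heat shock, dual specificity phosphatase and acute phase or iron genes were chosen after the largest changes were seen. Where a probe was not well above background on any of the 3 arrays of a group, the change is given as a bound ("at least"). The bound was set from the lowest signal among probes well above background after loess and Aquantile. Such bounds are open to dye bias because the dye orientations were unequal. The log2 values printed beside a bound depend on the background handling.

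Simulated ratios for 13179 genes held 200 changed genes. The same test code recovered 61.2% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2. All were in the right direction, with 11 false among 185 calls. In simulated lists of random genes, 5 of 5 lists shifted by 0.5 and 0 of 5 unshifted lists were called by camera. The 5 shifted lists were also called with an estimated correlation. The simulation drew independent noise centred on 0 and left out loess, dye effects and the probe filter. It also changed far fewer genes than the 9303 called in the data. It therefore checks the code of the tests and does not give error rates for these data. All 3 arrays lay on the same slide, so the slide could not be used as a block. The replicate number joins the treated and untreated RNA of an array, and the paired ratio is the unit tested; fits of the separate channels are among the alternatives. The alternatives covered a dye term, other background corrections, the scanner software's log ratio, median centring, scaling between arrays, the authors' table, other filters, the mean over probes, another variance prior, array weights, a fold threshold, the separate channels and leaving out each replicate. An alternative that centres each array on the tested genes was chosen after seeing the data.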

Results

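Adiponectin is a hormone secreted by fat cells that acts on macrophages, among other cells. The arrays compared gene expression in mouse bone marrow-derived macrophages given adiponectin (12 µg/ml for 18 h) with that in untreated macrophages. Each of the 3 arrays held 1 treated and 1 untreated RNA sample, and the labels call them biological replicates. Treated channels had 46.9%, 47.5% and 43.9% of probes well above background on replicates 1, 2 and 3, and untreated channels had 54.3%, 53.4% and 53.9%. The log2 ratios of treated over untreated correlated across the 13179 tested genes at r = 0.947 between replicates 1 and 2, 0.968 between replicates 1 and 3 and 0.943 between replicates 2 and 3, where genes are not independent replicates. The number of arrays limits the precision of every value below.

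The comparison asked which transcripts differ after 18 h of adiponectin. Inflammatory genes were among the largest rises. Ptgs2, which encodes the inducible prostaglandin synthase COX-2, rose by 6.16 ± 0.083 on the log2 scale (moderated SE, n = 3 arrays), or 71.5-fold. The cytokine genes Il6 and Il1b rose by 5.76 ± 0.097 and 5.14 ± 0.12. Receptor genes of the macrophage surface were among the largest falls, such as the mannose receptor gene Mrc1 (-3.90 ± 0.090), the lectin gene Clec10a (-3.57 ± 0.098) and the chemokine receptor gene Ccr2 (-4.00 ± 0.12). In all, limma with Benjamini-Hochberg adjustment called 3229 genes higher (24.5%) and 6074 lower (46.1%) of 13179, and 9268 of the 9303 called genes had the same sign in all 3 arrays. At 2-fold or more, 896 genes were higher and 1663 lower, while at 8-fold or more 83 were higher and 19 lower. The 2-fold counts were 1384 and 2366 with a normexp offset of 0, and 1566 and 2789 in the scanner software's log ratio. The lower share of the calls was 65.3%, and it was 51.0% (4638 higher, 4835 lower) when each array was centred on the tested genes, whose median was -0.17 with loess over all probes. With median centring in place of loess, limma called 0 genes in either direction (5314 at an unadjusted p under 0.05), and the median of all tested genes was -1.03. The medians of the 23 gene lists were then lower too, and those below 0 with loess lay between -1.98 and -1.18. All values with median centring carry part of a difference between the unequal dye orientations.

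The other genes among the 12 largest rises encode signals, receptors and enzymes. Cxcl3, a neutrophil-attracting chemokine, rose by 5.31 ± 0.11, and Tnfsf9, the ligand of the costimulatory receptor 4-1BB, by 5.22 ± 0.092. Adora2b, an adenosine receptor, rose by 5.13 ± 0.086, and Hcar2, the niacin and ketone body receptor, by 4.90 ± 0.12, though another probe of Hcar2 gave 2.55. Hspa1a, an inducible heat shock protein, rose by 5.12 ± 0.094, and Dusp2, a phosphatase of MAP kinases, by 5.04 ± 0.084. Ccr7, the chemokine receptor that guides cells to lymph nodes, rose by 4.97 ± 0.082. Saa2, an acute phase protein gene, was not well above background in untreated cells on any of the 3 arrays. It was at least 24.5-fold higher in treated cells (limma adjusted p = 3.19e-08). Its log2 value depended on the processing, at 4.90 here, 7.09 with a normexp offset of 0 and 8.47 in the scanner software's log ratio. The adjusted p of the 12 largest rises and of the 12 largest falls was at most 1.86e-07 in limma.

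The largest falls included sensors and surface proteins of the macrophage. Tlr13, a receptor for bacterial ribosomal RNA, had a log2 change of -4.10 ± 0.10, and Ifitm6, of the interferon-induced transmembrane family, one of -4.11 ± 0.089. Gcnt1, a glycan-branching enzyme, had a log2 change of -4.06 ± 0.10, Ptpro, a receptor tyrosine phosphatase, of -3.44 ± 0.079 and Timp2, a metalloproteinase inhibitor, of -3.36 ± 0.089. A dimmer probe gave -2.31 for Gcnt1, -1.31 for Timp2 and -1.28 for Rcbtb2. Rnf150 (-3.28 ± 0.12, or -1.72 as the mean over its probes), Rcbtb2 (-3.21 ± 0.093) and Ifit1bl1 (-3.17 ± 0.10) also fell. The 3 probes of Mfsd6 ranged from -3.29 to -0.14, and the brightest gave -3.29 ± 0.088 and their mean -1.43.

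**Figure D1:**
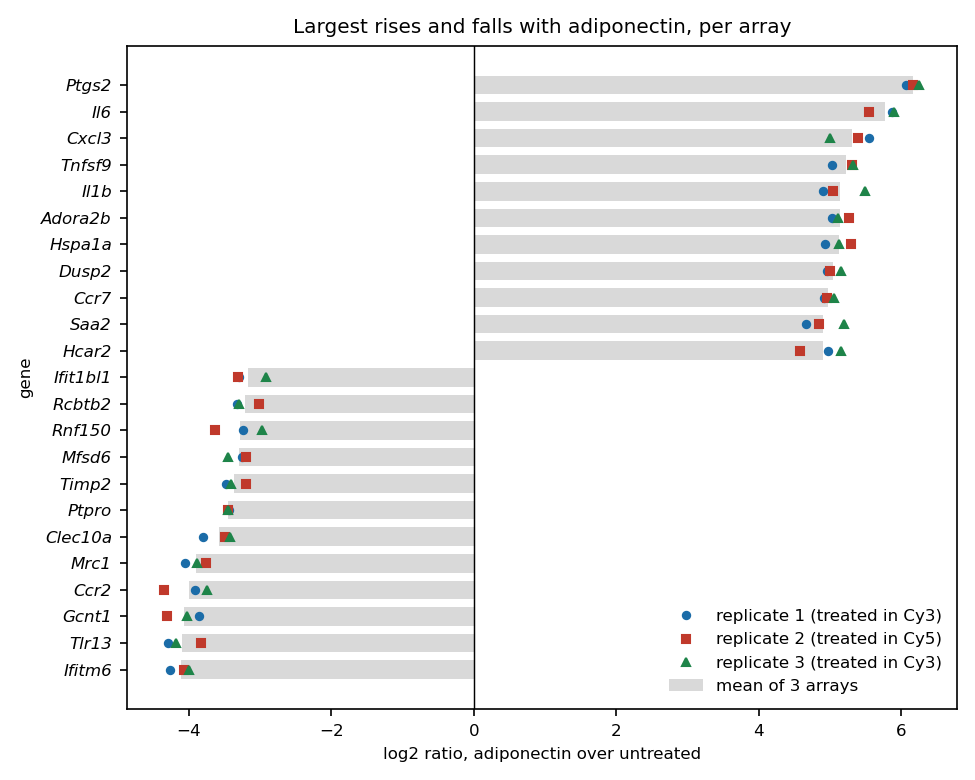
Log2 ratios of treated over untreated (horizontal axis) for 11 of the 12 genes with the largest rise and the 12 with the largest fall (vertical axis). Bars are means of 3 arrays and points the arrays, with the dye of the treated RNA given in the legend. All 3 arrays lie on the same side of 0 for each gene, as the rule that chose the genes required. The means run from Ptgs2 at 6.16 to Ifitm6 at -4.11.

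The lists of inflammatory genes moved upward together. Of 21 measured inflammatory cytokines and chemokines, 19 rose and none fell, with a median log2 change of 2.88, or 1.73 with median centring in place of loess. Il6 and Cxcl3 led, followed by Il1b and by Cxcl1 (4.85 ± 0.081), another neutrophil attractant. Their order depended on the processing: with a normexp offset of 0, Cxcl3 was at 6.67, Il6 at 6.27, Cxcl1 at 5.53 and Il1b at 5.33. Tnf, which encodes a central inflammatory cytokine, rose by 3.04 ± 0.11. The monocyte-attracting chemokine genes Ccl2 (-0.16) and Ccl7 (-0.12) did not pass. The list was called higher by camera (adjusted p = 2.48e-11), with an adjusted p = 0.319 with an estimated correlation. Of 20 measured targets of the inflammatory transcription factor NF-kB, 19 rose over all genes and 20 when adjusted over the list alone, and none fell, with a median of 2.02, or 0.92 with median centring. Malt1, a protease of NF-kB signalling, rose by 4.10 ± 0.089, the NF-kB inhibitors Nfkbia and Tnfaip3 by 3.51 ± 0.094 and 3.19 ± 0.10, and the costimulatory receptor gene Cd40 by 3.11 ± 0.094. Camera gave an adjusted p = 8.73e-13, and an adjusted p = 0.319 with an estimated correlation. Of 22 measured inflammatory effector genes, 20 rose and none fell, with a median of 2.02, or 0.99 with median centring. Nos2, the inducible nitric oxide synthase, rose by 3.61 ± 0.10. Slc7a2, an arginine transporter not well above background in untreated cells on any array, was at least 9.70-fold higher (limma adjusted p = 3.86e-08). Its log2 value depended on the processing, at 3.44 here, 5.52 with a normexp offset of 0 and 7.23 in the scanner software's log ratio. Saa3, an acute phase gene, rose by 3.74 ± 0.29, with 3.18, 4.89 and 3.15 on replicates 1, 2 and 3, and its dye coefficient of 0.86 passed (limma adjusted p = 0.0121). The effector list was called higher (camera adjusted p = 1.06e-12, and adjusted p = 0.319 with an estimated correlation).

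Most genes that restrain Toll-like receptor signalling rose. Of 20 measured negative regulators, 16 rose and 4 fell, with a median of 1.25, or 0.17 with median centring in place of loess. Socs3, a suppressor of cytokine signalling, rose by 3.30 ± 0.085, Il1rn, the interleukin-1 receptor antagonist, by 3.26 ± 0.084 and Tnip1, a partner of Tnfaip3, by 2.72 ± 0.080. Irak3, an inhibitory kinase homologue, rose by 1.16 ± 0.11, though it was at -0.01 ± 0.50 with median centring in place of loess. Il10, an anti-inflammatory cytokine gene, rose by 1.24 ± 0.092, or 1.91 in the scanner software's log ratio. Sigirr (-1.49), Inpp5d (-1.61), Ptpn6 (-0.69) and Trim30a (-0.67) fell. Camera gave an adjusted p = 3.80e-06, and an adjusted p = 0.319 with an estimated correlation. Among 20 measured Toll-like receptors and adaptors, 4 rose and 12 fell (5 and 12 when adjusted over the list alone), with a median of -0.47. Tlr4, the receptor of bacterial lipopolysaccharide, fell by 2.98 ± 0.11 on the log2 scale and Tlr3, a sensor of double-stranded RNA, by 1.52 ± 0.081, while Ticam1, the adaptor of both, rose by 1.83 ± 0.099. Tlr3 was at -2.27 with a normexp offset of 0 and at -2.58 in the scanner software's log ratio. That list was not called (camera adjusted p = 0.399, and adjusted p = 0.728 with an estimated correlation).

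Interferon-stimulated, antigen presentation and alternative activation genes moved both ways. Of 26 measured interferon-stimulated genes, 7 rose and 13 fell (7 and 14 when adjusted over the list alone), with a median of -0.40. Gbp5, a guanylate-binding protein gene, rose by 1.90 ± 0.16, with 1.35 on replicate 2 against 2.05 and 2.30, while Ifi44 (-1.75 ± 0.10), the DNA sensor gene Ifi204 (-1.48 ± 0.098) and the interferon signalling gene Stat2 (-1.45 ± 0.097) fell. The list was not called (camera adjusted p = 0.652, and adjusted p = 0.872 with an estimated correlation). Of 20 measured antigen presentation genes, 4 rose and 10 fell, with a median of -0.28. The costimulatory receptor gene Cd40 rose by 3.11 ± 0.094 and the class II gene H2-Ab1 by 1.14 ± 0.083. The costimulatory genes Cd86 and Cd80 fell by 1.37 ± 0.091 and 1.18 ± 0.090 on the log2 scale, with -0.57 for the dimmer probe of Cd80. That list was not called either (camera adjusted p = 0.717, and adjusted p = 0.825 with an estimated correlation). Of 17 measured genes of alternative activation, the state induced by interleukin-4, 10 rose and 6 fell. The median was 0.25 and turned to -0.23 with median centring in place of loess, the mean was -0.31, and camera leaned upward without a call (adjusted p = 0.212, and adjusted p = 0.728 with an estimated correlation). Mrc1 and Clec10a fell most, the nuclear receptor gene Pparg fell by 2.17 ± 0.10 on the log2 scale and the folate receptor gene Folr2 by 1.24 ± 0.087. Arg1, which encodes the arginine-degrading enzyme arginase, was at 0.25 ± 0.096 (limma adjusted p = 0.0410), and its call was lost without replicate 1 (adjusted p = 0.0809), without replicate 2 (0.170), with array weights (0.0528), with separate channels (0.0994), with median centring in place of loess (0.601) and with a required log2 change of 1. Its value was 0.15 without replicate 2, 0.41 in the authors' table, 0.43 with each array centred on the tested genes, 0.67 with a normexp offset of 0 and 0.97 in the scanner software's log ratio. Over all alternatives but median centring, its limma adjusted p ranged from 0.00235 to 0.170.

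The lists of lipid genes differed in direction. None of 17 measured cholesterol efflux genes and targets of LXR, the sterol-sensing receptor, rose and 15 fell, with a median of -0.58. The lipase gene Lpl (-2.43 ± 0.10, and -1.36 with its dimmer probe), Smpdl3a (-1.91 ± 0.092), the apolipoprotein genes Apoe (-1.75 ± 0.085) and Apoc1 (-1.54 ± 0.12) and the cholesterol exporter gene Abca1 (-1.48 ± 0.090) fell. The list was called lower (camera adjusted p = 0.00503, and adjusted p = 0.385 with an estimated correlation). Of 25 measured cholesterol biosynthesis genes, 13 rose and 7 fell, with a median of 0.26 that turned to -0.74 with median centring in place of loess. Insig1, a regulator of sterol synthesis, rose by 2.59 ± 0.11, and the pathway enzymes Mvd and Fdps by 2.54 ± 0.081 and 1.49 ± 0.11. The brightest probe of Fdft1, squalene synthase, gave 1.1 ± 0.080, the other -0.30 and their mean 0.40. The brightest was at -0.05 ± 0.49 with median centring in place of loess. Camera called this list higher (adjusted p = 0.0157, and adjusted p = 0.385 with an estimated correlation). Of 19 measured lipid uptake and storage genes, 6 rose and 12 fell, and 6 and 7 passed when each array was centred on the tested genes. The scavenger receptor gene Marco rose by 3.19 ± 0.11, the triglyceride synthesis gene Dgat2 by 3.15 ± 0.098 and the lipid droplet gene Hilpda by 2.46 ± 0.095, while the endocytic receptor gene Lrp1 fell by 2.01 ± 0.089 on the log2 scale. The median of that list was -0.27, its mean 0.07 and camera leaned upward without a call (adjusted p = 0.890, and adjusted p = 0.895 with an estimated correlation).

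Most measured genes of fatty acid oxidation fell. Of 20 measured members of that list, which includes PPAR targets, 2 rose and 15 fell, with a median of -0.77. The oxidation enzymes Acaa2 and Acadm were at -1.76 ± 0.080 and -1.73 ± 0.091, while the nuclear receptor gene Ppard rose by 2.01 ± 0.081. The list was called lower (camera adjusted p = 0.0157, and adjusted p = 0.584 with an estimated correlation). Of 30 measured oxidative phosphorylation genes, 3 rose and 19 fell (3 and 20 when adjusted over the list alone), with a median of -0.32. With each array centred on the tested genes, 4 rose and 11 fell. Sdha, a subunit of complex II, was at -1.02 ± 0.11 and the ATP synthase genes Atp5a1 and Atp5c1 at -0.77 ± 0.11 and -0.58 ± 0.097. Cycs, cytochrome c, rose by 0.97 ± 0.082 but was at -0.10 ± 0.61 with median centring in place of loess. The mean over probes was -0.35 for Atp5c1 and 0.61 for Cycs. Camera did not call that list (adjusted p = 0.281, and adjusted p = 0.728 with an estimated correlation). Of 25 measured glycolysis and hypoxia genes, 4 rose and 13 fell, with a median of -0.30. The glycolytic regulator gene Pfkfb3 rose by 3.26 ± 0.084, Ankrd37 by 1.97 ± 0.083 and the glucose transporter gene Slc2a1 by 1.52 ± 0.12, while Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell by 1.89 ± 0.10 on the log2 scale. That list was not called (camera adjusted p = 0.652, and adjusted p = 0.872 with an estimated correlation).

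More stress response genes rose than fell. Of 22 measured genes of oxidative stress and of its regulator NRF2, 16 rose and 2 fell. Their median of 0.76 turned to -0.31 with median centring in place of loess. Hmox1, the haem-degrading enzyme, rose by 2.36 ± 0.097, the metallothionein gene Mt2 by 1.84 ± 0.088, and the redox genes Txnrd1 and Gclm by 1.70 ± 0.11 and 1.62 ± 0.12. Camera called the list higher (adjusted p = 8.98e-06, and adjusted p = 0.584 with an estimated correlation). Of 20 measured genes of the unfolded protein and integrated stress response, 10 rose and 3 fell (11 and 1 with each array centred on the tested genes), with a median of 0.20 that turned to -0.74 with median centring in place of loess. The members that rose most were Ddit4, an inhibitor of the growth kinase mTOR (3.80 ± 0.10), the transcription factor gene Cebpb (2.64 ± 0.091), the phosphatase subunit gene Ppp1r15a (1.87 ± 0.092) and the serine synthesis gene Psat1 (1.26 ± 0.086, and 0.58 with its dimmer probe), whereas the chaperone gene Hspa5 (0.02) and Ddit3 (0.01), classical markers of the unfolded protein response, did not pass. This list was called higher (camera adjusted p = 0.00574, and adjusted p = 0.584 with an estimated correlation). Of 23 measured lysosome and autophagy genes, 4 rose and 17 fell, with a median of -0.53. The protease gene Ctss (-1.97 ± 0.17), the hexosaminidase gene Hexa (-1.70 ± 0.097), Lamp1 (-1.49 ± 0.19) and the autophagy gene Atg7 (-1.41 ± 0.089, and -0.61 with its dimmer probe) fell. On replicate 2 Ctss was at -1.35 and Lamp1 at -0.80, against -2.23 and -2.33 and against -1.74 and -1.93 on the other arrays. The list was not called (camera adjusted p = 0.0993, and adjusted p = 0.713 with an estimated correlation).

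Of 28 measured cell cycle genes, 6 rose and 17 fell, with a median of -0.53. The DNA replication genes Mcm6 (-2.07 ± 0.081) and Rrm2 (-1.86 ± 0.082, or -2.96 in the scanner software's log ratio) fell, while Mki67, a marker of dividing cells, rose by 3.27 ± 0.098 with both of its probes above 3.25, and the cyclin gene Ccne1 by 2.51 ± 0.10. The list was not called (camera adjusted p = 0.177, and adjusted p = 0.631 with an estimated correlation). Of 21 measured matrix and protease genes, 12 rose and 6 fell, with a median of 0.35 that turned to -0.42 with median centring in place of loess. The collagenase gene Mmp13 rose by 3.45 ± 0.088 and the metalloproteinase inhibitor gene Timp1 by 2.46 ± 0.12, opposite to Timp2. Camera called the list higher (adjusted p = 0.0173, and adjusted p = 0.608 with an estimated correlation).

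Of 22 measured complement, Fc receptor and clearance genes, 2 rose and 17 fell, with a median of -0.87. Gas6, a ligand that bridges dying cells to phagocytes, was at -2.70 ± 0.085, and the complement peptide receptor genes C3ar1 and C5ar1 were at -2.42 ± 0.082 and -2.27 ± 0.087. Fcgr2b, the inhibitory Fc receptor gene, rose by 2.15 ± 0.11. Camera called the list lower (adjusted p = 0.00531, and adjusted p = 0.387 with an estimated correlation). Of 21 measured chemokine and growth factor receptors, 4 rose and 12 fell, with a median of -0.32. Ccr7 and the chemerin-binding receptor gene Ccrl2 (2.69 ± 0.11) rose, while Ccr2 and the fractalkine receptor gene Cx3cr1 (-2.39 ± 0.14, and -1.61 with its dimmer probe) fell. That list was not called (camera adjusted p = 0.353, and adjusted p = 0.608 with an estimated correlation).

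Most measured genes of adiponectin's own signalling fell. Of 17 measured members, 1 rose and 12 fell (3 and 10 with each array centred on the tested genes), with a median of -0.64. The receptor genes Adipor1 and Adipor2 were at -0.43 ± 0.089 and -0.64 ± 0.10 (limma adjusted p = 0.00254 and 0.000563), or -0.26 and -0.47 relative to the median of all tested genes, and neither passed with a required log2 change of 1. Cdh13, the gene of the adiponectin-binding T-cadherin, was not well above background in either group. Prkaa1 and Prkag2, subunits of the energy-sensing kinase AMPK, fell by 1.94 ± 0.089 and 1.99 ± 0.095 on the log2 scale, and Appl2, an adaptor of the receptors, by 1.26 ± 0.085. Camera called the list lower (adjusted p = 0.0338, and adjusted p = 0.477 with an estimated correlation), and the call was lost with a normexp offset of 0 (adjusted p = 0.0699) and with the scanner software's log ratio (0.106), in a range of 0.00823 to 0.477 over the alternatives other than median centring. Of 15 common reference genes, 2 rose and 6 fell, with a median of -0.24. Gusb (-2.20 ± 0.14), the transferrin receptor gene Tfrc (-1.92 ± 0.090, its 3 probes from -1.92 to -0.26, with a mean of -1.19, and -2.92 in the scanner software's log ratio) and Hprt (-1.05 ± 0.10) fell. Actb (-0.24) and Gapdh (-0.24) did not pass. That list was not called (camera adjusted p = 0.379, and adjusted p = 0.728 with an estimated correlation).

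**Figure D2:**
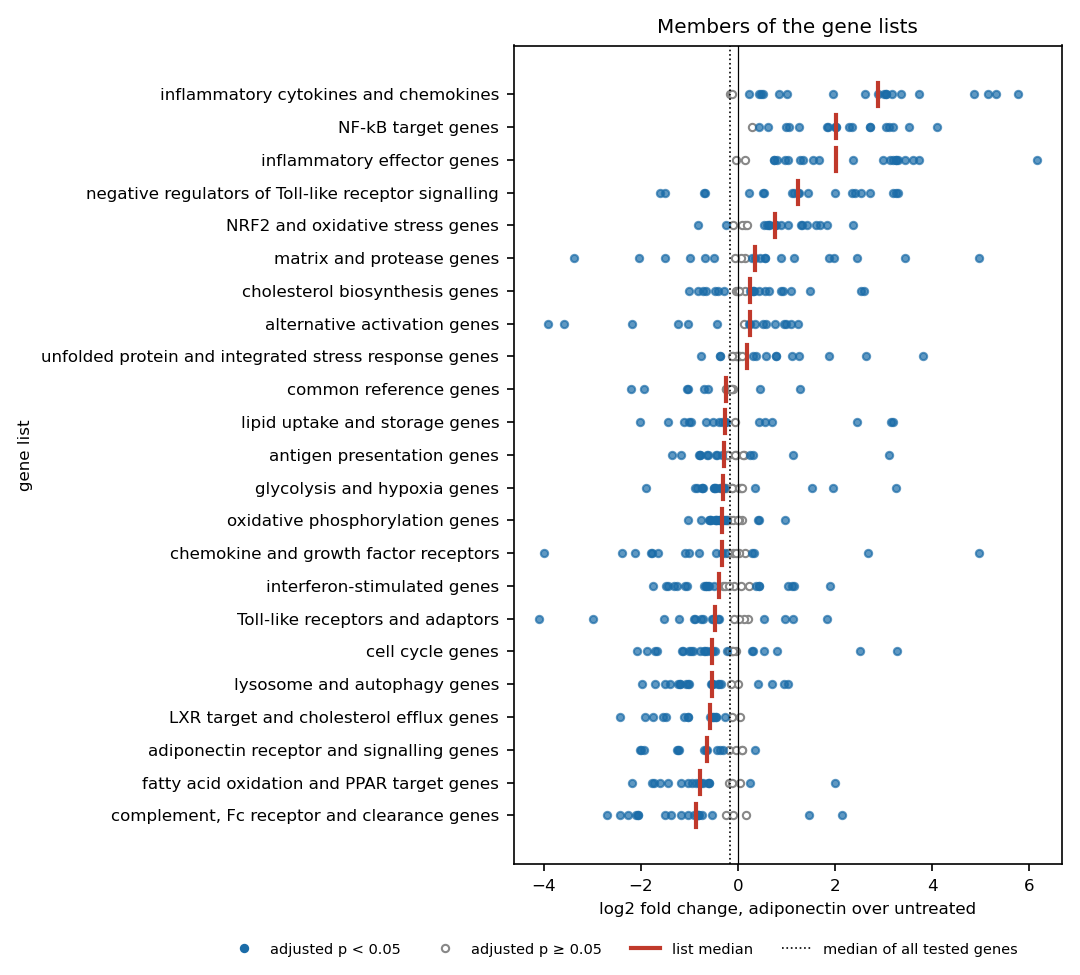
Log2 fold changes of treated over untreated (horizontal axis) for the measured members of the 23 gene lists (vertical axis), sorted by list median. Filled points had an adjusted p under 0.05 in limma, open points did not, red bars are list medians and the dotted line is the median of all tested genes (-0.17). The inflammatory lists lie farthest right (medians of 2.02 to 2.88) and complement, Fc receptor and clearance genes farthest left (-0.87). With median centring in place of loess the medians of alternative activation, cholesterol biosynthesis, NRF2, unfolded protein response and matrix genes turn negative, and the other list medians are lower too.

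Markers of the macrophage itself fell. All 11 measured macrophage markers were lower, from -0.80 for the integrin gene Itgam to -3.90 for Mrc1, with a median of -1.70 and -1.79 ± 0.18 for Csf1r, the receptor of CSF-1. The list was called lower (camera adjusted p = 0.000764, and adjusted p = 0.439 with an estimated correlation). No other marker list was called by camera. Of 9 monocyte and progenitor markers 1 rose and 8 fell (adjusted p = 0.0888), of 7 dendritic cell markers 2 rose, Ccr7 and Zbtb46, and 1 fell (adjusted p = 0.0839), and of 6 fibroblast markers 3 rose, or 2 when adjusted over the list alone (adjusted p = 0.0888). With each array centred on the tested genes, 6 dendritic cell and 6 fibroblast markers rose, and 4 rather than 8 monocyte and progenitor markers fell. The medians of the dendritic cell and fibroblast lists (0.17 and 0.17) turned negative with median centring in place of loess (-0.77 and -0.10). Osteoclast markers (4 rose and 4 fell of 10, adjusted p = 0.700), neutrophil markers (3 and 4 of 10, 0.977) and endothelial markers (1 and 3 of 6, 0.977) moved both ways. Of 5 T and NK cell markers 2 rose and 1 fell (adjusted p = 0.253), or 3 and 0 with each array centred on the tested genes. Of the lists too short to test, 1 B cell marker rose and 2 fell of 4, 1 erythroid marker rose and 1 fell of 4, 2 mast cell and basophil markers rose and 1 fell of 4, and 2 adipocyte markers rose of 3. With an estimated correlation the lowest adjusted p was 0.319 among the 23 gene lists and 0.439 among the marker lists. Except where given, the counts adjusted over the list alone equalled those over all genes. Fry, which asks whether a list's own genes move, called 19 of the 23 gene lists in 1 direction and 23 in either. It also called all 8 tested marker lists in 1 direction (adjusted p from 0.000164 to 0.0333), which does not compare them with other genes.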

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

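The tests of explanations in this part and their thresholds were chosen after the results were seen, and the centring on tested genes was an alternative added after seeing the data. Of 6018 measured probes named only by a genomic region, which no comparison of genes used, 2650 passed in limma with Benjamini-Hochberg adjustment, 1479 higher and 1171 lower, of which 241 and 130 changed at least 2-fold. The share that passed was 44.0%, below the 70.6% of the tested genes. They drew attention because they show a signal outside the named genes. The regions below were picked from the largest rises and falls among regions with at least 2 measured probes, all of which passed. On build mm9 the region of chromosome 16 from 84702353 to 84710928 was higher by 3.51 on the log2 scale over 3 probes marked R in the region name and by 2.11 over 3 probes marked F. That of chromosome 9 from 14460976 to 14488051, marked F, was higher by 2.73 over 5 probes, and that of chromosome 6 from 11996975 to 12037300, marked F, was at -1.77 over 4 probes. No explanation was tested for them.

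The 9303 calls were set against the 3 other assignments of treated and untreated that exchange the channels of 1 array. With the real assignment included there are 4, of which 1 gave as many calls, and the highest other number was 0 (37 genes at an unadjusted p under 0.05 in the highest). Assignments this few cannot give a share under 0.05.

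More genes were lower than higher, with 65.0% of calls of at least 2-fold on the lower side. A dye effect from the unequal dye orientations is argued against as the whole cause, since a dye term left 64.7% of those calls lower, and so are probes seen in the untreated channel alone, since probes above background in all 6 readings left 63.9%. Loess centres each array on all probes, many of them dim, and with each array centred on the tested genes 50.8% were lower. That centring itself sets the split of all calls, so it cannot decide whether the loess centring or a real excess of falls may be the source. A treatment effect stays open beside it.

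All 11 measured macrophage markers were lower in treated cells. A smaller share of macrophages in the treated wells would lower them by about the same factor, but their log2 changes spanned 3.1, against a largest SE of 0.18. Unequal mixing is thus argued against as the whole cause, and a change of expression within the macrophages after adiponectin stays open as a hypothesis.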

How the results depend on the processing

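Of 108 named genes tested, only Arg1 changed its call under any alternative but median centring and the fold threshold, and none changed direction there. With median centring in place of loess, limma called 0 genes higher and 0 lower (5314 at an unadjusted p under 0.05, lowest adjusted p 0.0741), and no named gene passed. The signs of Fdft1 (-0.048 ± 0.49), Cycs (-0.10 ± 0.61) and Irak3 (-0.014 ± 0.50) were then negative, but each value was smaller than its SE. The arrays' medians were then -1.48, -0.06 and -1.67 on replicates 1, 2 and 3, against -0.16, -0.14 and -0.20 with loess. The medians with median centring differed with the dye orientation. Since the orientations were unequal, the gene and list values with median centring carry part of that difference. A dye effect alone, equal on all arrays, would have changed the sign of the array median on replicate 2, but all array medians lay below 0. Loess may thus remove more than a difference between the dyes, and the source of the rest was not tested. A required log2 change of 1 left 896 higher and 1663 lower and ended the calls of 6 named genes (Adipor1, Adipor2, Arg1, Atp5a1, Atp5c1 and Cycs), by its construction. Under the other alternatives the counts stayed within 1.5 times of 3229 and 6074 (not so for all counts at 2-fold or more), and leaving out 1 replicate gave 2761 to 3150 higher and 5368 to 6144 lower. Centring on the tested genes, chosen after seeing the data, gave 4638 and 4835, and 8064 of the calls were shared, all in the same direction. Separate-channel fits with the array as a replicate block gave 3260 and 6154 and without the block 3245 and 6142, with an intraspot correlation of 0.012; Arg1 lost its call in both. With an estimated correlation 0 of 23 gene lists and 0 marker lists were called by camera (fry called 19 of the gene lists and all 8 tested marker lists). With 2 residual degrees of freedom, this loss of calls cannot tell correlated genes from too few arrays. Marker lists called numbered 3 with the scanner software's log ratio, 2 with median centring and 2 with no filter on dim probes, against 1, and the cause was not tested. The slide block was not run, since all arrays shared the slide. Dim signals limit fold sizes: Slc7a2 was at 3.44 with the normexp offset of 50 and at 5.52 with an offset of 0.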

Other observations

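The heat shock, acute phase and iron, and phosphatase lists and the test of the agonist in this part were chosen after the data were seen; the inflammatory and interferon-stimulated lists were not. Heat shock and co-chaperone genes rose with adiponectin: of 16 measured, 14 rose, 1 fell and 1 did not pass, with a median log2 change of 1.41. Beside Hspa1a, the small heat shock protein gene Hspb1 rose by 3.47 ± 0.088 (SE), the co-chaperone gene Hsph1 by 2.83 ± 0.080 and the inducible chaperone gene Hsp90aa1 by 2.40 ± 0.091. Of 18 measured acute phase and iron genes, 13 rose and 3 fell, with a median of 1.20. Hp, haptoglobin, rose by 3.67 ± 0.091, Hamp, which encodes the iron hormone hepcidin, by 3.81 ± 0.12 and Lcn2, a protein that binds bacterial iron carriers, by 3.12 ± 0.080. The 3 that fell were the iron exporter gene Slc40a1 (-1.29 ± 0.079), the iron importer gene Slc11a2 (-1.16 ± 0.088) and the transferrin receptor gene Tfrc (-1.92 ± 0.090, its probes from -1.92 to -0.26). Of 17 dual specificity phosphatase genes, some of which act on MAP kinases, 7 rose and 7 fell: Dusp4 rose by 3.91 ± 0.091 and Dusp1 by 2.53 ± 0.11, while Dusp6 was at -3.03 ± 0.090. These lists were picked from the largest changes, so their counts are not independent evidence.

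Inflammatory genes rose while interferon-stimulated genes did not move together. A Toll-like receptor agonist in the protein preparation might raise the same inflammatory genes, and if it gave a lasting interferon response most interferon-stimulated genes would be higher at 18 h. Of 26 measured, 26.9% were called higher and 50% lower, near the 24.5% and 46.1% of all tested genes. The prediction, set at 70% or more higher, was thus not met. The bound set for the opposite reading, 70% or more lower, was not met either. That bound does not follow from the absence of an agonist, so the test cannot decide. An agonist without a lasting interferon response was not tested, and the hypothesis of an agonist stays open. Ifnb1, the interferon beta gene, named here after its value was seen, was higher by 1.85 ± 0.11 (limma adjusted p = 1.94e-06). No sample analysed here holds a treatment that would separate adiponectin from such an agonist.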
